A study of Mus musculus with 15 samples.

How the data were processed

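RNA from pancreatic tumours of αSMA-tk positive mice, extracted with Trizol per the labels, was measured on Illumina MouseWG-6 v2 bead arrays, with 15 arrays in 5 groups of 3. The authors made biotinylated cRNA with a MessageAmp kit and, per the labels, used GenomeStudio, whose version is not stated. The deposited unnormalized tables hold, per probe and array, a bead summary signal in intensity units, neither background subtracted nor normalized between arrays. Beside each signal these deposited tables give a detection p-value of the probe against the negative controls of the same array. One table holds 12 arrays and the other the 3 anti-CTLA4 arrays. The deposited value table of the series also holds intensity on a linear scale. Each of its columns was a straight line function of the same array's unnormalized signal, with absolute residuals of at most 0.0862 to 0.104. How the authors chose slope and offset is not known.

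Depth on an array is signal over background. Of 45281 probes per array, 17446 to 19707 (38.5% to 43.5%) had a detection p-value under 0.05, and the median signal was 95.2 to 142.1. The column medians in the deposited value table were 24.2, 26.2 and 28.2 for the early control arrays, 18.7, 19.7 and 19.3 for early ablation, 21.9, 24.2 and 16.5 for late control, 19.5, 22.9 and 24.0 for late ablation, and 22.1, 24.6 and 25.0 for anti-CTLA4. The number of arrays limits the precision of each comparison.

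The unnormalized signals were background corrected from the detection p-values (normexp, limma 3.58.1 in R 4.3.3, offset 16), quantile normalized and put on the log2 scale. Of the probes, 34885 carry 1 gene symbol, 18 several and 10378 none. No symbol changed when matched by Entrez identifier. Per symbol, the probe with the highest mean was kept, and probes with no or several symbols each stood as a feature. Features needed a detection p-value under 0.05 on at least 3 arrays of the fit, which left 14633 features (11650 with a symbol) over 12 arrays and 15098 (11924 with a symbol) over 15. Where every array of a group missed detection, a lower bound is given as an at-least fold when 2 groups are compared. For it, signals of that group below the lowest detected signal of their array were raised to that signal. The bound allows only for undetected signal and not for the spread between arrays, so it is no guaranteed minimum change. The difference between stages has no such bound, and genes undetected in a group are named there.

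Linear models with group means were fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Early ablation against early control, late ablation against late control, late control against early control, and the late minus the early ablation effect came from the 12 arrays of the first table. Late ablation with anti-CTLA4 against late ablation alone came from all 15 arrays normalized together. There the anti-CTLA4 group and its own table coincide. Comparisons that share a group share its arrays and are not independent. Acta2 also had an exact two-sided permutation test, in which 3 against 3 arrays cannot go below p = 0.1.

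The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 26 lists: smooth muscle and pericyte, fibroblast, collagen and extracellular matrix, TGF-beta response, endothelial, hypoxia and glycolysis, mesenchymal transition, epithelial, tumor stem cell markers, pan T cell, cytotoxic effector, regulatory T cell and checkpoint, B and plasma cell, macrophage, neutrophil and inflammatory chemokine, interferon response, MHC class II, acinar, islet, ductal and mucinous lesion, proliferation, p53 and DNA damage, immediate early and heat shock, adipocyte, erythrocyte and hepatocyte. The 22 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, a rotation test of whether a list's genes move on balance one way. A list is given with its members' mean log2 difference.

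Up to 8 genes per direction past the threshold were named in each comparison, filled up to 5 by the smallest unadjusted p. In lists that passed, the 2 members with the smallest p in the list's direction and the 2 brightest members were named, and in other lists 2 members. Acta2, Col1a1, Foxp3, Ctla4, Cd8a, Vegfa, Pecam1, Snai1 and Mki67 were named throughout where measured. Cd8a was detected on at most 1 array and Mki67 has no probe, so neither was tested. The Foxp3 probe used was bright and varied little over all arrays. Whether it follows regulatory T cells was not tested.

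The pipeline was tested on simulated data made from these arrays, with 50 features raised or lowered at each of 4 sizes. Normal noise was drawn independently per feature and array, with each feature's spread within groups. Correlation between genes and structure among the arrays were thus left out, so the counts below do not measure error or power under them. At log2 changes of 1, 2, 3 and 4 it recovered 22, 43, 48 and 50 of 50 in the early comparison, with 7 unchanged features called. The late comparison recovered 18, 42, 48 and 50 with 9 such calls, and the anti-CTLA4 comparison 23, 36, 44 and 50 with 9.

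The titles number the arrays of each group 1 to 3. Whether equal numbers pair arrays was checked by the correlation of their deviations from the group means. Late control and late ablation arrays of equal number correlated at r = 0.59, 0.39 and 0.14. With other numbers the highest values were -0.35, 0.27 and 0.09, so only number 1 stood out clearly. In the other comparisons equal numbers did not pair. With a replicate block over both stages, the late comparison gave 0 genes and 2 lists. With only the late groups in the block, a fit added later, it gave 0 genes, and the islet and interferon response lists also passed.

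Alternatives were a larger offset of 50, no background correction, median scaling, cyclic loess, no detection filter, a stricter filter of detection p under 0.01 on 6 arrays, all probes as features, only the groups compared, a trended and robust variance, array weights, the replicate block, the authors' value table with values below 1 set to 1, and leaving out each array in turn. A slide block was not run, as the files name no slide. Alternatives added later are named with their results. Counts were also set against other splits of the same arrays, 10 per pair of groups and 100 drawn with seed 7 for the comparison by stage, and later the 80 by stage that part the late arrays of equal number. Correlations across arrays had permutation tests with 1e+05 resamples.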

Results

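Pancreatic ductal adenocarcinoma (PDAC) tumours of αSMA-tk positive mice on a mixed C57BL/6 and Balb/c background were profiled on 15 bead arrays. The transgene makes dividing cells that use the promoter of Acta2, the gene of alpha smooth muscle actin and a marker of myofibroblasts, sensitive to ganciclovir. The labels name 5 groups of 3 arrays. Early and late controls received no ganciclovir, early ablation received it at the stage of pancreatic intraepithelial neoplasia, a precursor lesion, and late ablation at the PDAC stage. In the last group late ablation was combined with an antibody against CTLA4, a checkpoint receptor of T cells. Between 38.5% and 43.5% of the 45281 probes were detected on each array. Rank correlations over the 105 pairs of arrays ranged from 0.889 to 0.973. Late control array 1 and late ablation array 1 matched each other better than any other array (0.972). The labels do not say whether each array comes from a separate animal, so p-values measure only the spread between these arrays. All values are log2 normalized signal, differences are log2, and each group has n = 3.

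No difference in Acta2 passed between ablated and control arrays. On early ablation arrays it averaged 12.52 ± 1.37 (SD), against 11.78 ± 0.567 on early control arrays, a difference of 0.74 (SE 0.772, exact permutation p = 0.4), which ranged from 0.21 to 1.51 when single arrays were left out. On late ablation arrays it averaged 11.78 ± 1.07, against 11.82 ± 1.31 on late control arrays (difference -0.05, or 0.01 with median scaling, exact permutation p = 0.9). With anti-CTLA4 it averaged 10.89 ± 1.07, against 11.77 ± 1.06 with late ablation alone (-0.88, SE 0.785, exact permutation p = 0.4). Late and early controls differed by 0.04 (exact permutation p = 1). The smallest p that 3 against 3 arrays can give is 0.1, so these tests could not pass 0.05. Adjusted limma p for the same contrasts was 0.798, 1, 0.826 and 0.992. Smooth muscle outside the myofibroblasts also expresses Acta2.

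**Figure D1:**
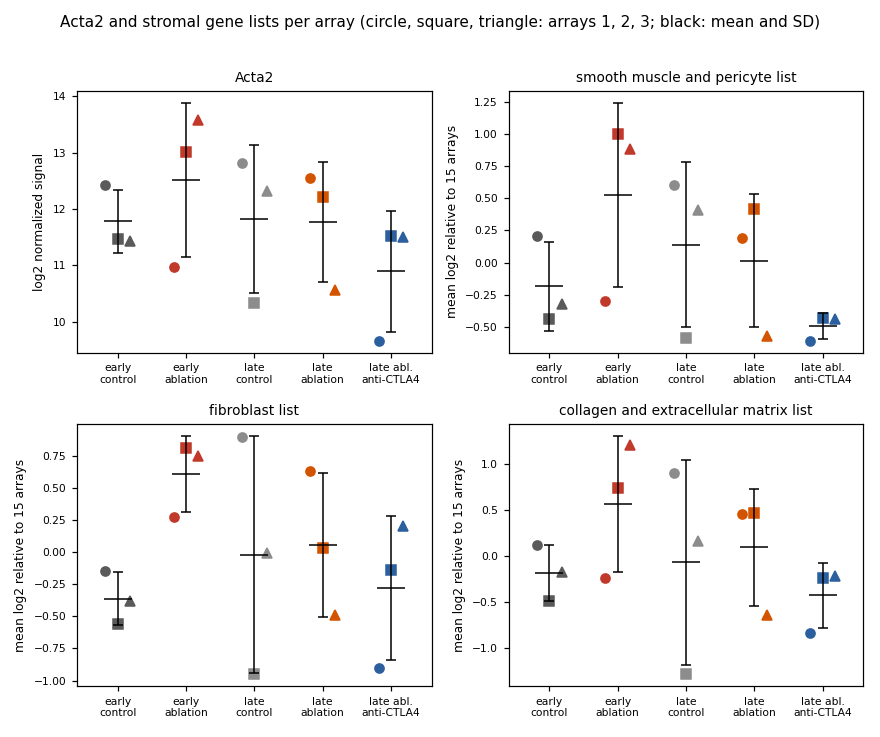
Log2 normalized signal of Acta2, and mean log2 level relative to the mean of 15 arrays of the smooth muscle and pericyte, fibroblast, and collagen and extracellular matrix lists, in the 5 groups (circle, square and triangle are arrays 1, 2 and 3, and black marks are the mean and SD, n = 3). Acta2 averaged 12.52 on early ablation and 11.78 on early control arrays, and the fibroblast list was higher on each early ablation array than on each early control array.

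The first comparison asks how tumours differ when αSMA-positive cells were targeted at the precursor stage. Genes of fibroblasts, matrix and macrophages were higher on the arrays labelled early ablation than on early control arrays. Genes of the interferon response and of ductal and mucinous lesions were lower. Late control arrays, without ganciclovir, were also lower than these early control arrays in interferon, ductal and proliferation genes. Their means were -0.78, -0.45 (which did not pass) and -0.81. For these lists a trait of the early control arrays cannot be told apart from ablation. All 17 measured members of the fibroblast list were higher on early ablation arrays, by 1.01 on average (camera adjusted p = 5.7e-06, adjusted p = 0.47 with an estimated correlation). Pdgfra, a receptor carried by fibroblasts, was 8.84 ± 0.664 (SD, n = 3) against 7.03 ± 0.363, a difference of 1.81 (SE 0.561, limma adjusted p = 0.518). Decorin, Dcn, was 12.70 ± 0.473 against 11.04 ± 0.188 (1.65, SE 0.537), while Thy1 differed by only 0.38 (SE 0.483). Collagen and extracellular matrix genes were 0.75 higher, in 20 of 22 members (adjusted p = 1.9e-05, adjusted p = 0.47 with an estimated correlation). That mean was 1.16 without early ablation array 1 and 0.44 without array 3, and in this list array 1 (-0.24 relative to the mean of 15 arrays) lay below 2 of the 3 early control arrays. Mmp14, a membrane-bound matrix protease, differed by 0.93 (SE 0.302) and biglycan, Bgn, by 0.99 (SE 0.341).

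Smooth muscle and pericyte genes were 0.71 higher on the arrays labelled early ablation, in 14 of 15 members (adjusted p = 0.0011, adjusted p = 0.47 with an estimated correlation), and 1.13 higher without early ablation array 1. Mylk, the myosin light chain kinase of smooth muscle, was 10.59 ± 0.396 (SD, n = 3) against 8.84 ± 0.194 (limma adjusted p = 0.455). Rgs5, a pericyte gene, differed by 0.65 (SE 0.346), and the bright Tpm1, for tropomyosin, by -0.19 (SE 0.241), or 0.01 with median scaling. The TGF-beta response list was 0.58 higher, in 10 of 11 members (adjusted p = 4.2e-05, adjusted p = 0.47 with an estimated correlation). Tgfb2, a TGF-beta ligand, was 5.99 ± 0.19 against 4.73 ± 0.0787 on early control arrays, none of which detected it, so it was at least 1.81-fold higher (limma adjusted p = 0.316). Bmp1 differed by 0.83 (SE 0.326) and Ccn2 by 0.34 (SE 0.239). Endothelial genes were 0.48 higher, in 13 of 15 members (adjusted p = 0.0063, adjusted p = 0.47 with an estimated correlation). Among them Vwf, the von Willebrand factor of endothelium, differed by 1.57 (SE 0.37). That call ended without early control array 2 (0.29, adjusted p = 0.12) and without early ablation array 3 (0.33, adjusted p = 0.11). Mesenchymal transition genes were 0.53 higher, in 9 of 10 members (adjusted p = 0.015, adjusted p = 0.47 with an estimated correlation), with Vim at 1.69 (SE 0.566) and Zeb2 at 0.67 (SE 0.262). Without early ablation array 3 the list stood at 0.37 (adjusted p = 0.11), and median scaling also ended the call (adjusted p = 0.074).

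Macrophage genes were 0.83 higher, in 16 of 17 members (adjusted p = 3.8e-05, adjusted p = 0.47 with an estimated correlation). The mannose receptor Mrc1 differed by 1.60 (SE 0.561) and the lysozyme gene Lyz2 by 0.89 (SE 0.47). B and plasma cell genes were 0.65 higher, in 5 of 6 members (adjusted p = 0.016, adjusted p = 0.47 with an estimated correlation). Without early ablation array 1 they stood at 0.26 (adjusted p = 0.2), and median scaling, no detection filter, array weights and the authors' values also ended the call (adjusted p = 0.21, 0.15, 0.1 and 0.08). The list ranged from 0.26 to 1.14 without single arrays. Mzb1, a gene of antibody-secreting cells, differed by 1.60 (SE 0.54), and Cd79b, part of the B cell receptor, by 1.11 (SE 0.666). Without single arrays Mzb1 ranged from 0.95 to 2.37 and Cd79b from 0.26 to 1.54. Interferon response genes were 0.70 lower on the log2 scale (mean -0.70), in 11 of 14 members (adjusted p = 0.00025, adjusted p = 0.47 with an estimated correlation). The guanylate-binding protein gene Gbp2 differed by -1.46 (SE 0.551) and Ifit3, an interferon-induced gene, by -1.24 (SE 0.48). Early control arrays 2 and 3 carried the highest interferon levels of all 15 arrays (0.94 and 1.23 above the mean of 15 arrays). The same arrays were the only ones with bright H2-Ea, which C57BL/6 mice do not transcribe. Genetic background and ablation therefore cannot be fully told apart for these genes, nor for the other genes and lists of the early comparison. Without early control array 1 the interferon list stood at -1.12, and without array 3 at -0.39. T cell lists did not pass, with pan T cell at 0.15 (adjusted p = 0.5) and regulatory T cell and checkpoint at 0.09 (adjusted p = 0.53). Only 7 of 16 and 11 of 18 members of these lists were measured. MHC class II genes averaged 0.26, with a median of -0.04 (adjusted p = 0.66). The neutrophil and inflammatory chemokine list averaged 0.21 (adjusted p = 0.55).

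Ductal and mucinous lesion genes had a mean of -0.67 on the arrays labelled early ablation, with 12 of 13 members lower (adjusted p = 0.00042, adjusted p = 0.47 with an estimated correlation). Gkn1, a gastric mucosal protein, differed by -0.71 (SE 0.288), Ctse, cathepsin E, by -0.57 (SE 0.232), and Tff2, a trefoil factor, by -0.42 (SE 0.236). Without early ablation array 1 the list stood at -0.23 (adjusted p = 0.1). Epithelial genes had a mean of -0.22, or 0.03 with median scaling, with 12 of 15 lower (adjusted p = 0.041, adjusted p = 0.47 with an estimated correlation). Muc1 differed by -0.52 (SE 0.222) and keratin 19, Krt19, by -0.51 (SE 0.222). The epithelial call ended without early control array 2 (-0.22, adjusted p = 0.052) or 3 (-0.18, adjusted p = 0.11), and without early ablation array 1 (-0.18, adjusted p = 0.15) or 3 (-0.22, adjusted p = 0.059). Proliferation genes had a mean of -0.35, or 0 with median scaling, with 17 of 19 lower (adjusted p = 0.016, adjusted p = 0.75 with an estimated correlation). The replication licensing genes Mcm4 and Mcm2 differed by -0.36 (SE 0.239) and -0.62 (SE 0.468), and Cenpa by 0.02 (SE 0.526). That list stood at -0.10 without early control array 3 (adjusted p = 0.46) and at -0.04 without early ablation array 1 (adjusted p = 0.77). Its mean ranged from -0.67 to -0.04 without single arrays. The p53 and DNA damage list was 0.27 higher, in 9 of 11 members (adjusted p = 0.049, adjusted p = 0.47 with an estimated correlation), with Plk2 at 0.68 (SE 0.212) and Trp53inp1 at 0.86 (SE 0.355). It missed the threshold without early control array 1 (0.28, adjusted p = 0.099) or 3 (0.23, adjusted p = 0.15), without early ablation array 1 (0.10, adjusted p = 0.4), and with median scaling (0.56).

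The remaining lists did not pass in the early comparison. Acinar genes, which encode digestive enzymes, had a mean of -0.30 (15 of 22 lower, adjusted p = 0.33). Early ablation array 1 stood apart at -3.57 in the acinar list, against -1.98 to 1.91 on the other arrays, and was the lowest in the ductal list (-1.21) and the highest in the MHC class II list (1.95). Islet genes averaged 0.43 (adjusted p = 0.16), hypoxia and glycolysis 0.28 (adjusted p = 0.19), tumor stem cell markers 0 (adjusted p = 0.99), and immediate early and heat shock genes -0.01 with a median of 0.04 (adjusted p = 0.93). The lists with too few measured members averaged 0.14 for cytotoxic effector, -0.11 for adipocyte, 0.75 for erythrocyte and 0.51 for hepatocyte genes, untested.

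No single gene passed in the early comparison (limma, 0 of 14633 features, smallest adjusted p = 0.0918). At unadjusted p under 0.05 there were 1276 features, 711 higher and 565 lower, where 732 would be expected by chance, and 999 to 2409 under the alternatives. Some alternatives test more or fewer features, so that chance count does not apply to them, here or below. The count of genes at unadjusted p under 0.05, early ablation, was 820 without early control array 2, 724 without array 3 and 806 without early ablation array 1. Limma called 9 features without early ablation array 3, and 2 and 1 without early control arrays 1 and 2. In 3120 features (21.3%) the groups did not overlap, where chance gives 10%. Detection itself did not overlap either, with 38.5% to 39.4% of probes on early control and 41.3% to 43.5% on early ablation arrays. A difference in signal over background therefore cannot be told apart from ablation, also for genes undetected on early control arrays. The smallest p belonged to Kdm2b, a histone demethylase gene, at -1.75 (SE 0.226), from a single bright probe that averaged 8.42 ± 0.428 (SD) on early control arrays. Late control arrays differed from these early control arrays in Kdm2b too, by -1.64. Next came C1s1, a complement protease gene, which no early control array detected and which was at least 2.37-fold higher (6.38 ± 0.37 against 4.45 ± 0.0751, SD, n = 3, limma adjusted p = 0.29). Hspb1, a small heat shock protein gene, differed by 1.91 (SE 0.349), Fmod, fibromodulin of the matrix, by 1.68 (SE 0.299), Nccrp1 by -2.59 (SE 0.531) and Cyp2c65 by -2.23 (SE 0.501), each with an adjusted p of 0.316 or above. Adjusted over the list alone, Mylk, Tgfb2 and Vwf passed, and no list member passed over all genes. Of the other fixed genes, Vegfa differed by 0.90 (SE 0.476), Pecam1 by 0.50 (SE 0.424), Ctla4 by 0.46 (SE 0.403), Snai1 by 0.75 (SE 0.708), Col1a1 by 0.66 (SE 0.876, from 0.02 to 1.19 without single arrays), and Foxp3 by -0.08 (SE 0.187), or 0.26 with median scaling. No list call in any comparison holds with an estimated correlation between genes, and fry called 0 lists in each (smallest adjusted p 0.26 here). With median scaling the median log2 difference of all genes was 0.253 in this comparison, 0.149 between the controls and -0.235 in the difference between stages.

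The late comparison asks the same of targeting at the PDAC stage. MHC class II genes, which present antigen to helper T cells, had a mean of -1.11 on late ablation arrays, with 9 of 9 members lower than on late control arrays (camera adjusted p = 4.7e-05, adjusted p = 0.88 with an estimated correlation). H2-Ab1 was 8.34 ± 0.619 (SD, n = 3) against 10.16 ± 1.06, and the invariant chain gene Cd74 was 8.59 ± 0.675 against 10.52 ± 1.05 (both with an adjusted limma p of 1). H2-DMb1 differed by -0.93 (SE 0.406). That call was kept without any 1 of the 6 arrays. Hypoxia and glycolysis genes were 0.39 higher, in 14 of 15 members (adjusted p = 0.0023, adjusted p = 0.88 with an estimated correlation). The glycolytic genes Pgk1, Ldha and Aldoa differed by 0.50 (SE 0.239), 0.35 (SE 0.229) and 0.38 (SE 0.291), and Pdk1, which restrains pyruvate oxidation, by 0.53 (SE 0.338). This rested on late ablation array 3, which stood at 1.36 relative to the mean of 15 arrays. The same array was highest in the immediate early and heat shock list, at 1.0 against 0.38 or less on the others, a level chosen after it was seen. Without it the hypoxia list was at -0.13 (adjusted p = 0.64), without late control array 3 at 0.32 (adjusted p = 0.051), and with no detection filter at 0.31 (adjusted p = 0.09).

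Stromal lists showed no difference that passed in the late comparison. Fibroblast genes averaged 0.08 (adjusted p = 0.78), collagen and extracellular matrix 0.16 (adjusted p = 0.29), smooth muscle and pericyte -0.13 (adjusted p = 0.65) and endothelial -0.13 (adjusted p = 0.29). Interferon response genes averaged -0.26 (11 of 14 lower), pan T cell genes -0.29 (7 of 7 lower) and proliferation genes -0.29 (16 of 19 lower), each with an adjusted p of 0.069. A replicate block with only the late groups, added later, called interferon response (-0.28, camera adjusted p = 0.027) and islet genes (-0.51, adjusted p = 0.0055). Proliferation did not pass there (adjusted p = 0.12). Between late arrays of equal number, pan T cell genes differed by -0.21, -0.40 and -0.27, but proliferation genes by -0.26, 0.57 and -1.16 and interferon genes by -0.40, 0.19 and -0.56, a split made after these values were seen. B and plasma cell genes averaged -0.35 (5 of 6 lower, adjusted p = 0.15) and macrophage genes -0.18 (12 of 17 lower, adjusted p = 0.29). Limma called 0 of 14633 features (smallest adjusted p 1). At unadjusted p under 0.05 there were 308, 146 higher and 162 lower, against 732 by chance and with 161 to 996 under the alternatives, and the groups did not overlap in 644 (4.4%, where chance gives 10%). Leaving out late control array 1 raised the count of genes at unadjusted p under 0.05, late ablation, to 1081, and leaving out late ablation array 1 or 2 raised it to 558 or 679. Psmb9, an immunoproteasome subunit induced by interferon, had the smallest p (-0.95, SE 0.206, adjusted p = 1). Adjusted over the list alone it was the single member to pass, in the interferon list. Cdhr5, a cadherin of epithelial brush borders, differed by -1.71 (SE 0.46), Tcf12 by 0.65 (SE 0.176) and Mospd2 by 0.95 (SE 0.26). Galnt6, which starts O-glycan chains on mucins, was 5.72 ± 0.425 (SD, n = 3) against 4.88 ± 0.111, undetected on the late control arrays, so at least 1.63-fold higher (limma adjusted p = 1). Met, the receptor of hepatocyte growth factor, was 4.68 ± 0.0305 against 5.42 ± 0.247, undetected on the late ablation arrays, so at least 1.29-fold lower (limma adjusted p = 1). Foxp3 differed by -0.16 (SE 0.187), Ctla4 by -0.19 (SE 0.403), Pecam1 by -0.31 (SE 0.424), Snai1 by -0.34 (SE 0.708), Vegfa by 0.05 (SE 0.476) and Col1a1 by 0.09 (SE 0.876).

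**Figure D2:**
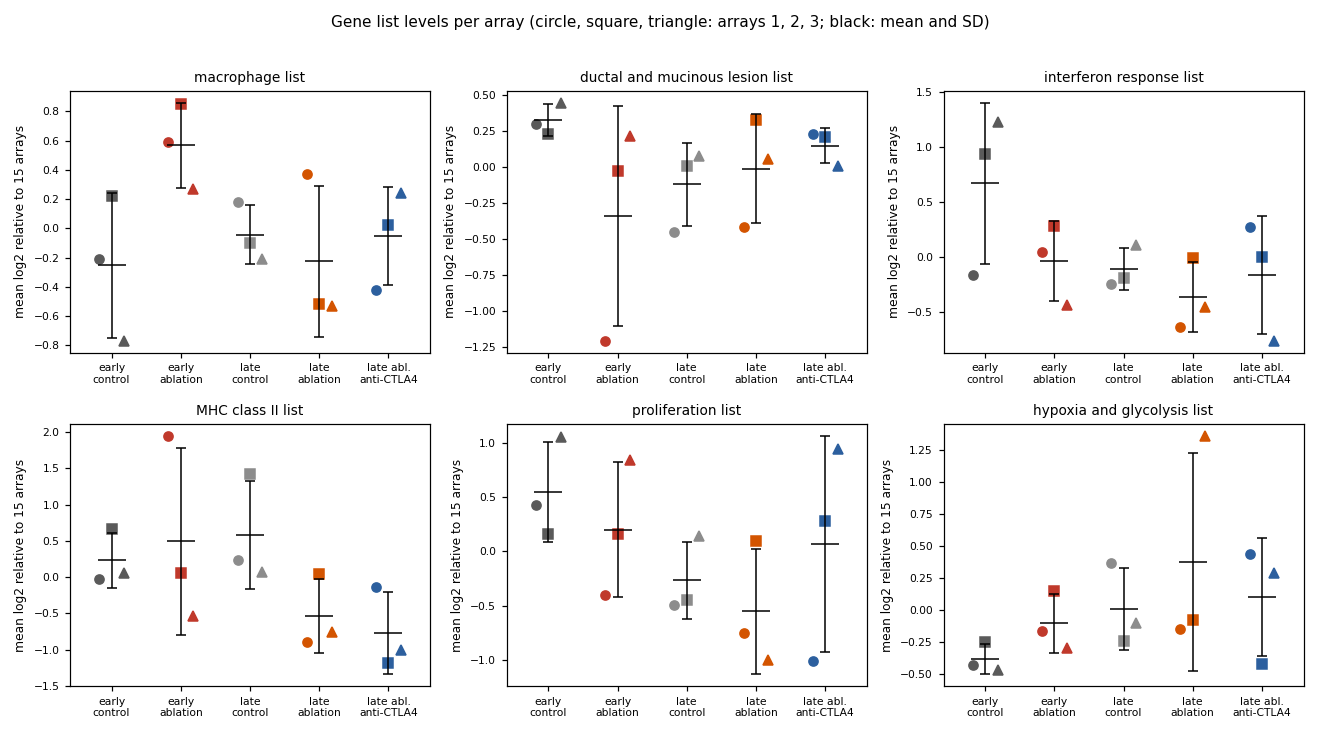
Mean log2 level, relative to the mean of 15 arrays, of the macrophage, ductal and mucinous lesion, interferon response, MHC class II, proliferation, and hypoxia and glycolysis lists in the 5 groups (circle, square and triangle are arrays 1, 2 and 3, and black marks are the mean and SD, n = 3). Early control arrays 2 and 3 are highest in the interferon list (0.94 and 1.23), and late ablation array 3 is highest in the hypoxia and glycolysis list (1.36).

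Whether the ablation effect differed between stages was tested as the late effect minus the early effect. The early control arrays enter this difference, so genetic background cannot be fully told apart here either. Macrophage genes differed most clearly, by -1.01 (16 of 17 lower, camera adjusted p = 6.4e-05, adjusted p = 0.5 with an estimated correlation), with Lyz2 at -1.73 (SE 0.665) and Mrc1 at -1.73 (SE 0.794). Fibroblast genes differed by -0.93 (15 of 17 lower, adjusted p = 0.00033, adjusted p = 0.5 with an estimated correlation), with Dcn at -2.22 (SE 0.759) and Pdgfra at -1.97 (SE 0.793). Without late control array 1 the fibroblast list stood at -0.45 (adjusted p = 0.063), and over all single arrays left out it ranged from -1.42 to -0.45. The TGF-beta response list differed by -0.53 (9 of 11 lower, adjusted p = 0.0014, adjusted p = 0.5 with an estimated correlation), with Tgfb2 at -0.94 (SE 0.335), and stood at -0.31 without late ablation array 3. B and plasma cell genes differed by -1.0 (6 of 6 lower, adjusted p = 0.0026, adjusted p = 0.5 with an estimated correlation), with Mzb1 at -2.20 (SE 0.764). They stood at -0.61 without early ablation array 1 and at -1.57 without array 3. Ductal and mucinous lesion genes went the other way, by 0.78 (11 of 13 higher, adjusted p = 0.0022, adjusted p = 0.5 with an estimated correlation), with the mucin Muc5ac at 3.57 (SE 1.53) and Gkn1 at 0.95 (SE 0.407). Without late control array 1 the ductal list stood at 0.61 (adjusted p = 0.053), and without early ablation array 1 at 0.34, still past the threshold. No early control array detected Tgfb2 and no late ablation array detected Mzb1, so the sizes given for these genes rest in part on background signal.

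Smooth muscle and pericyte genes differed between stages by -0.84 (13 of 15 lower, adjusted p = 0.0027, adjusted p = 0.5 with an estimated correlation), with Mylk at -2.27 (SE 0.663) and Rgs5 at -1.46 (SE 0.49). The call ended without early ablation array 3 (-0.66, adjusted p = 0.052), late control array 1 (-0.61, adjusted p = 0.062) or late ablation array 3 (-0.55, adjusted p = 0.067). Collagen and extracellular matrix genes differed by -0.59 (20 of 22 lower, adjusted p = 0.0027, adjusted p = 0.6 with an estimated correlation), and stood at -0.27, -0.10 and -0.22 without the same 3 arrays (adjusted p = 0.15, 0.58 and 0.17), but at -1.20 without late control array 2 and -1.0 without early ablation array 1. Median scaling also ended that call (adjusted p = 0.057). Endothelial genes differed by -0.61 (13 of 15 lower, adjusted p = 0.0022, adjusted p = 0.5 with an estimated correlation), with Vwf at -1.70 (SE 0.523). They stood at -0.38 without late control array 1 (adjusted p = 0.084) and at -0.39 without late ablation array 3 (adjusted p = 0.071). MHC class II genes differed by -1.37 (8 of 9 lower, adjusted p = 0.0027, adjusted p = 0.56 with an estimated correlation), with H2-Ab1 at -2.60 (SE 1.06). The call ended without early ablation array 1 (-0.64), without late control array 2 (-0.93, adjusted p = 0.11) and with array weights (-0.65, adjusted p = 0.34), which also ended the ductal call (0.47). Islet hormone and related genes differed by -0.83 (11 of 13 lower, adjusted p = 0.042, adjusted p = 0.6 with an estimated correlation), with somatostatin, Sst, at -2.37 (SE 1.05) and insulin, Ins2, at -2.49 (SE 1.85). The islet call was kept under 3 of 13 alternatives and in 5 of the 12 fits that left out an array. It ended without early control arrays 1 (-0.50) and 3 (-0.72), early ablation array 1 (-0.35), late control arrays 1 (-0.58) and 2 (-0.85), and late ablation arrays 2 (-0.63) and 3 (-0.71).

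No single gene passed the test of the difference between stages (limma, 0 of 14633, smallest adjusted p 0.612). At unadjusted p under 0.05 there were 680 features, 283 higher and 397 lower, against 732 by chance and with 485 to 1423 under the alternatives. That count was 415 without early control array 3 and 1160 without late ablation array 1. Limma called 4 features without early ablation array 3 and 1 without early control array 2. Higd1b, a gene of pericytes, differed by -2.13 (SE 0.347, adjusted p = 0.612), Prkg1, a kinase that relaxes smooth muscle, by -1.70 (SE 0.315), Kdm2b by 1.88 (SE 0.319) and Nccrp1 by 3.62 (SE 0.75). Higd1b was detected on no early control and no late ablation array, so its size rests in part on background signal. Acta2 differed by -0.79 (SE 1.09), Col1a1 by -0.57 (SE 1.24), Vegfa by -0.86 (SE 0.673), Pecam1 by -0.81 (SE 0.6), Snai1 by -1.09 (SE 1.00), Ctla4 by -0.64 (SE 0.57) and Foxp3 by -0.08 (SE 0.264). Across the 14633 features, which are not independent replicates, the early and the late effect correlated at r = 0.061 and rho = 0.067. In 47 features both effects had an unadjusted p under 0.05, against 26.9 expected of independent lists, with equal sign in 26 and opposite sign in 21.

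Between late and early controls, both without ganciclovir, the proliferation and interferon lists passed. As many lists came from 9 of 10 splits of these arrays, the real one included. Proliferation genes had a mean of -0.81 on late control arrays, with 18 of 19 lower than on early control arrays (camera adjusted p = 5.7e-07, adjusted p = 0.93 with an estimated correlation). Mcm4 was 9.80 ± 0.3 (SD, n = 3) against 10.66 ± 0.265 (-0.85, SE 0.239, limma adjusted p = 0.325), Mcm3 differed by -1.18 (SE 0.377) and Cenpa by -0.60 (SE 0.526). Interferon response genes had a mean of -0.78, with 12 of 14 lower (adjusted p = 0.00031, adjusted p = 0.93 with an estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, differed by -1.61 (SE 0.578), Gbp2 by -1.24 (SE 0.551) and the transcription factor Irf1 by -0.29 (SE 0.286). The chemokine gene Cxcl9 was at least 2.15-fold lower, at 4.54 ± 0.125 (SD, n = 3) against 6.13 ± 1.12 (limma adjusted p = 0.353), detected on no late control array and on 2 of 3 early control arrays. Without single arrays the interferon list ranged from -1.2 to -0.43, the latter without early control array 3 (adjusted p = 0.18). Early control arrays 2 and 3, the highest in interferon genes, were also the only arrays with bright H2-Ea, which C57BL/6 mice do not transcribe. Genetic background and stage therefore cannot be fully told apart here.

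Of the other lists between the controls, ductal and mucinous lesion genes averaged -0.45 (12 of 13 lower, adjusted p = 0.22), islet genes 0.61 (adjusted p = 0.35), fibroblast genes 0.33 (adjusted p = 0.31) and macrophage genes 0.21 (adjusted p = 0.5). Limma called 0 of 14633 features (smallest adjusted p 0.167). At unadjusted p under 0.05 there were 1461, 741 higher and 720 lower, against 732 by chance, with 835 to 3678 under the alternatives and 881 without early control array 3. Without early control arrays 1 and 2 limma called 2 and 1. The groups did not overlap in 2623 features (17.9%, where chance gives 10%). Detection did not overlap either, with 39.7% to 43.2% of probes on late control and 38.5% to 39.4% on early control arrays. Sgk1, a kinase induced by serum and glucocorticoids, was 13.04 ± 0.268 (SD, n = 3) on late and 11.36 ± 0.339 on early control arrays (limma adjusted p = 0.272). Milr1, a receptor of mast cells, was 5.86 ± 0.117 against 4.80 ± 0.1 (SD, n = 3) and undetected on the early control arrays, so at least 1.66-fold higher (limma adjusted p = 0.272). Kdm2b differed by -1.64 (SE 0.226, adjusted p = 0.167) and Ddx58, the gene of the viral RNA sensor RIG-I, by -1.09 (SE 0.22). Both this comparison and the early one use the same early control arrays. Adjusted over the list alone, Twist1 in the mesenchymal list and Cd247 in the pan T cell list passed, as did Lpl and Lep in the adipocyte list and Rhag in the erythrocyte list, which were too short to test as lists. Vegfa, the endothelial growth factor, differed by 1.30 (SE 0.476, adjusted p = 0.411), Snai1 by 1.27 (SE 0.708), Pecam1 by -0.48 (SE 0.424), Col1a1 by 0.52 (SE 0.876), Ctla4 by -0.12 (SE 0.403), and Foxp3 by -0.16 (SE 0.187), or 0.02 with median scaling.

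Anti-CTLA4 arrays were compared with late ablation arrays, which asks what the antibody adds to late ablation. A single gene passed. D17H6S56E-5, which lies in the major histocompatibility complex between H2-K1 and Mog on the GRCm38.p6 assembly, was at background on all 3 anti-CTLA4 arrays (4.64 ± 0.232, SD, n = 3) and at 10.33 ± 1.11 on late ablation arrays. It was at least 37-fold lower (log2 difference -5.70, SE 0.446, limma adjusted p = 7.39e-05). The probe read 9.28 to 11.49 on all 12 arrays of the other groups, and a second probe was dim, at 4.35 to 5.99, and undetected on most arrays. The call was kept without any 1 of the 6 arrays (-6.21 to -5.12). The anti-CTLA4 arrays have a table of their own, so the group and any difference between tables cannot be told apart.

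**Figure D3:**
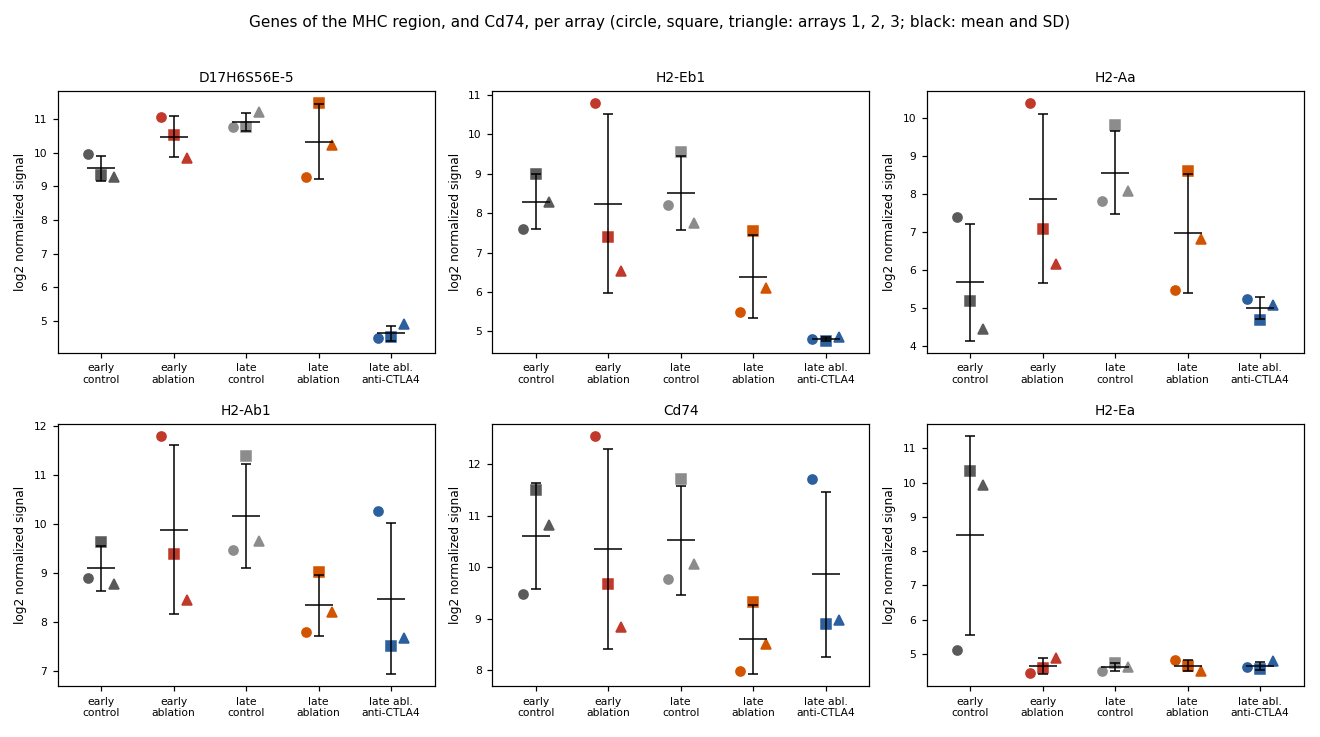
Log2 normalized signal of D17H6S56E-5, H2-Eb1, H2-Aa, H2-Ab1, Cd74 and H2-Ea in the 5 groups (circle, square and triangle are arrays 1, 2 and 3, and black marks are the mean and SD, n = 3), with H2-Eb1 and H2-Ea chosen after their values were seen. D17H6S56E-5 reads 4.49 to 4.90 on the anti-CTLA4 arrays and 9.28 to 11.49 on the other 12 arrays.

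Proliferation genes were 0.62 higher on anti-CTLA4 arrays, in 18 of 19 members (camera adjusted p = 0.0083, adjusted p = 0.93 with an estimated correlation). The mitotic genes Aurka, Cdc20 and Cenpa differed by 0.82 (SE 0.44), 1.25 (SE 0.728) and 0.97 (SE 0.725), and Mcm4 by 0.20 (SE 0.238). That call ended without late ablation array 1 (0.52, adjusted p = 0.079) or 3 (0.39, adjusted p = 0.11), and without anti-CTLA4 array 2 (0.51, adjusted p = 0.057) or 3 (0.17, adjusted p = 0.67). The proliferation mean ranged from 0.17 to 1.15 without single arrays. Collagen and extracellular matrix genes had a mean of -0.52, with 21 of 22 lower (adjusted p = 0.0083, adjusted p = 0.93 with an estimated correlation). Col1a2 differed by -1.70 (SE 0.727), Mmp14 by -0.74 (SE 0.285) and Bgn by -0.34 (SE 0.325). The collagen call ended without late ablation array 1 (-0.34, adjusted p = 0.24) or 2 (-0.34, adjusted p = 0.19), without anti-CTLA4 array 1 (-0.32, adjusted p = 0.28) and with array weights (-0.28, adjusted p = 0.28). The collagen mean ranged from -0.89 to -0.32 without single arrays. Immune lists did not pass, with pan T cell genes at 0.06 (adjusted p = 0.86), regulatory T cell and checkpoint genes at 0.21 (adjusted p = 0.13), interferon response genes at 0.20 (adjusted p = 0.32), macrophage genes at 0.17 (adjusted p = 0.45) and MHC class II genes at -0.24 (adjusted p = 0.76). Of the pan T cell and the regulatory T cell and checkpoint lists, only 7 of 16 and 13 of 18 members were measured. Acinar genes averaged -0.94 (19 of 22 lower, adjusted p = 0.087) and smooth muscle and pericyte genes -0.51 (13 of 15 lower, adjusted p = 0.075).

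Limma called 1 of 15098 features. At unadjusted p under 0.05 there were 1172, 613 higher and 559 lower, against 755 by chance and with 655 to 2402 under the alternatives, and the groups did not overlap in 1558 (10.3%, where chance gives 10%). Just short of the threshold were Ehmt1, a histone methyltransferase gene, at 1.74 (SE 0.256, adjusted p = 0.0708), and Psmb9 at 1.27 (SE 0.206, adjusted p = 0.071). Ino80d, of a chromatin remodelling complex, differed by 2.49 (SE 0.429) and Cbx5, the heterochromatin protein HP1 alpha, by 1.18 (SE 0.211), both with an adjusted p of 0.0796. Cdc25c, a phosphatase that starts mitosis, was 5.62 ± 0.228 (SD, n = 3) against 4.63 ± 0.0955, undetected on late ablation arrays, so at least 1.46-fold higher (limma adjusted p = 0.0796). Adjusted over the list alone, Psmb9 passed in the interferon list. Like D17H6S56E-5, Psmb9 lies between H2-K1 and Mog. Psmb8 and Tap1, of the same list, differed by only 0.32 (SE 0.463) and 0.10 (SE 0.351). Both this and the late comparison use the same late ablation arrays. Without late ablation array 1 limma called 9 features and without anti-CTLA4 array 1 it called 5. Foxp3, the transcription factor of regulatory T cells, differed by 0.24 (SE 0.185), and Ctla4 by 0.15 (SE 0.377). The Foxp3 probe was bright and nearly flat on all arrays, so it may not follow regulatory T cells. Vegfa differed by -0.38 (SE 0.467), Col1a1 by -0.41 (SE 0.814), Pecam1 by -0.10 (SE 0.406) and Snai1 by -0.03 (SE 0.654).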

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

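The splits by stage that part the late pairs and the tests for another MHC haplotype, for fewer MHC class II expressing cells and for exchanged arrays or groups were chosen after the results they address were seen. The remaining splits of the arrays, the acinar covariate and the difference between tables were not. The fibroblast list and D17H6S56E-5, to which that covariate and the difference between tables are applied below, were however picked by their results.

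A test of the difference between stages, as the late minus the early ablation effect, singled out 10 gene lists. The stromal ones were lower, with fibroblast at -0.93 (camera adjusted p = 0.00033, adjusted p = 0.5 with an estimated correlation), smooth muscle and pericyte at -0.84 (0.0027, adjusted p = 0.5 with an estimated correlation), collagen and extracellular matrix at -0.59 (0.0027, adjusted p = 0.6 with an estimated correlation), TGF-beta response at -0.53 (0.0014, adjusted p = 0.5 with an estimated correlation) and endothelial at -0.61 (0.0022, adjusted p = 0.5 with an estimated correlation). Of the immune lists, macrophage stood at -1.01 (6.4e-05, adjusted p = 0.5 with an estimated correlation), B and plasma cell at -1.0 (0.0026, adjusted p = 0.5 with an estimated correlation) and MHC class II at -1.37 (0.0027, adjusted p = 0.56 with an estimated correlation). Islet stood at -0.83 (0.042, adjusted p = 0.6 with an estimated correlation), and ductal and mucinous lesion, the single higher list, at 0.78 (0.0022, adjusted p = 0.5 with an estimated correlation). Chance is not excluded. Of 100 splits drawn, the real one included, 28 called as many lists (10 in the real split, at most 15 in another), 44 gave as many features at unadjusted p under 0.05 (680, at most 3952) and 100 as many genes past the threshold (0, at most 1066). An absolute correlation between the early and the late effect as large as the real 0.061 came from 82 of 100 splits (at most 0.436). Since late arrays of equal number deviate together, the 80 splits that part all 3 late pairs, the real one included, were also run, and chance is not excluded there either. As many lists came from 37 of 80 (at most 16 in another), as many features at unadjusted p under 0.05 from 8 of 80 (at most 1055), as many genes from 80 of 80 (0 in each), and as large a correlation from 31 of 40 (at most 0.368).

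D17H6S56E-5 was at background on all 3 anti-CTLA4 arrays and 9.28 to 11.49 on the other 12. Fewer cells with MHC class II on the anti-CTLA4 arrays are argued against as the whole cause, since D17H6S56E-5 differed from late ablation arrays by -5.70 (SE 0.446), while Cd74 differed by 1.27 (SE 0.941, carried by array 1 at 11.71) and H2-Ab1 by 0.14 (SE 0.838). A smaller loss can be neither shown nor excluded, since the class II genes did not move together. H2-Aa differed by -1.98 (SE 1.04, limma adjusted p = 0.676) and H2-Eb1 was at least 2.39-fold lower (adjusted p = 0.686). Both were dim on anti-CTLA4 array 1 too, where Cd74 was bright. H2-DMa differed by -0.18 (SE 0.585) and H2-DMb1 by 0.79 (SE 0.389). Another MHC haplotype in these mice, whose labels give a mixed background, stays open, since other features of the region passed an unadjusted p of 0.05 no more clearly than the rest (9 of 108 against 836 of 11815, odds ratio 1.19, 95% confidence interval 0.528 to 2.37, Fisher exact p = 0.571, and odds ratio 1.27, p = 0.439, without the class II list). H2-Ea, which C57BL/6 mice do not transcribe, was chosen after its values were seen. It was bright on early control arrays 2 and 3 and dim on all others, the anti-CTLA4 arrays included. D17H6S56E-5 was bright on arrays of both kinds, so the haplotype difference that H2-Ea marks does not go with its loss. A haplotype that H2-Ea does not mark stays open. A difference between the tables cannot be told apart from the group. It was probed by counting probes detected on all 12 other arrays and on none of the 3, of which there were 20 for anti-CTLA4 and 39 for early control, and only D17H6S56E-5 and H2-Eb1 among the 20 were over 2 log2 units lower, which are also the only 2 of them in the MHC region. The reverse count was highest for anti-CTLA4, at 26 probes, against 8, 14, 2 and 0 for early control, early ablation, late control and late ablation. An effect of the antibody also stays open, untested.

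Fibroblast genes averaged 1.01 higher on the arrays labelled early ablation, where the design would place fewer αSMA-positive cells. Acinar content, which was lowest on early ablation array 1, is argued against as the whole cause, since the difference was 1.01 (SE 0.489) without and 1.08 (SE 0.401) with the acinar level of each array as a covariate. The acinar list differed by only -0.30 between these groups, so the covariate could move the difference little. Across the 12 arrays fibroblast and acinar levels rose together, without passing (r = 0.43, permutation p = 0.16). Exchange of single arrays cannot be told apart, since 5 of 6 arrays ranked closer to their own group, while early ablation array 3 was nearer the controls (by -0.0098 in mean rank correlation) and no early control array was nearer the ablation group. Nor can an exchange of the whole groups, with which the Acta2 difference of 0.74 (SE 0.772) would be in keeping but which no value here decides. Genetic background stays open too, since bright H2-Ea was seen on early control arrays alone. So does a difference in signal over background, as detection was lower on each early control array than on each early ablation array. A change in the stroma that outlasts or follows ablation may be the cause and stays open, untested.

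Within a pair of groups, 3 against 3 arrays give 10 splits, too few for a share under 0.05. As many features at unadjusted p under 0.05 as in the real split came from 1 of 10 splits in the early comparison (1276, highest other 611), 9 of 10 in the late one (308, highest other 3685), 1 of 10 between the controls (1461, highest other 979) and 3 of 10 with anti-CTLA4 (1172, highest other 2280). As many lists came from 1 of 10 (13, highest other 12), 8 of 10 (2, highest other 9), 9 of 10 (2, highest other 9) and 8 of 10 (2, highest other 10). As many genes past the threshold came from 10 of 10 early (0, highest other 1), 10 of 10 late (0, highest other 883), 10 of 10 between the controls (0, highest other 3) and 2 of 10 with anti-CTLA4 (1, highest other 2). The split with 883 genes put late control array 1 and late ablation arrays 1 and 3 against the rest, which points to a structure of the late samples other than their groups. Late arrays of equal number deviated together, clearly so only for number 1 (r = 0.59, at most -0.35 with other numbers). The pairs numbered 2 and 3 are weak (0.39 against 0.27, and 0.14 against 0.09). The real split parts all 3 pairs, as do 3 others, which gave 0 genes each, 247, 379 and 506 features at unadjusted p under 0.05 (308 in the real split) and 9, 8 and 5 lists (2 in the real split).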

How the results depend on the processing

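The Xist covariate, the fits without the late control and late ablation arrays numbered 1, the fit without the genes between H2-K1 and Mog, the replicate block with only the groups compared, and, for lists, only the groups compared and array weights were chosen after the data were seen. Signal over background limits all results: at most 43.5% of probes were detected on an array. D17H6S56E-5 kept its direction and its call under 14 of 14 alternatives that measure it (-6.21 to -3.42, adjusted p 6.97e-06 to 0.0326). Of the lists in the early comparison, fibroblast (0.73 to 1.29), collagen (0.52 to 1.06), smooth muscle (0.48 to 1.03), TGF-beta response (0.40 to 0.88), macrophage (0.63 to 1.10) and interferon (-0.84 to -0.40) kept their calls under 11 of 13 alternatives and without each array in turn. Without single arrays, smooth muscle ranged from 0.48 to 1.13 (1.13 without early ablation array 1), collagen from 0.44 to 1.16 (0.44 and 1.16 without early ablation arrays 3 and 1) and interferon from -1.12 to -0.39 (without early control arrays 1 and 3). An estimated correlation and fry ended these calls, as they did all list calls in the 5 comparisons (0 called by each). A slide block was not run, since no slide is named. All probes were not used for lists, the trended and robust variance does not enter camera, and for the difference between stages only the groups compared are the same 12 arrays. Except where a construction is named, the cause of a change was not tested.

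In the early comparison 0 genes passed. Only the groups compared gave 1, array weights gave 23 (19 higher, 4 lower), and leaving out single arrays gave 0 to 9 (9 without early ablation array 3, 2 and 1 without early control arrays 1 and 2). Lists called without single arrays numbered 9 to 15. B and plasma cell lost its call with median scaling (adjusted p = 0.21), no filter (0.15), array weights (0.1) and the authors' values (0.08). The p53 list lost it with median scaling (at 0.56), weights (0.16) and the replicate block (0.066), proliferation with weights (0.13) and the authors' values (0.074), mesenchymal transition with median scaling (0.074), and epithelial with the strict filter (0.11), the authors' values (0.062) and the Xist covariate (0.065). Direction turned for Tpm1 with median scaling (0.01) and without single arrays (-0.31 to 0.03), Foxp3 with median scaling (0.26), Cenpa with the Xist covariate (-0.08) and without single arrays (-0.42 to 0.38), and without single arrays for Thy1 (-0.07 to 0.73) and Ctla4 (-0.03 to 0.72).

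In the late comparison 0 genes passed. The fit without the arrays numbered 1 called 1, Cdhr5 (-2.71, SE 0.217, adjusted p = 0.00488). Lists called went from 2 to 5 with median scaling, 1 with no filter, 6 with only the groups compared, 4 with array weights, 4 with the authors' values, 4 with the Xist covariate, 4 with the replicate block and only the groups compared, and 1 to 9 without single arrays (7, 9 and 1 without late control arrays 1, 2 and 3, and 6 without late ablation array 1 or 2). In that block fit the lists gained were islet (-0.51, adjusted p = 0.0055) and interferon response (-0.28, adjusted p = 0.027), pan T cell and B and plasma cell genes had too few measured members to be tested, and hypoxia and glycolysis stood at 0.38 (adjusted p = 0.013) and MHC class II at -1.21 (adjusted p = 5.8e-11), and the count of genes at unadjusted p under 0.05, late ablation, was 538. MHC class II kept its call under 13 of 15 alternatives (-1.33 to -0.75) and without each array in turn (-1.41 to -0.71). Hypoxia and glycolysis missed the threshold with no filter (0.31, adjusted p = 0.09) and ranged from 0.31 to 0.88 over the alternatives (0.88 without the arrays numbered 1) and from -0.13 to 0.67 without single arrays. Direction turned for Acta2 with median scaling (0.01), the Xist covariate (0.04), without the arrays numbered 1 (0.06) and without single arrays (-0.79 to 0.56), and for Col1a1 with no background correction (-0.04), array weights (-0.19) and without single arrays (-1.02 to 0.96). It also turned for Ctla4 with array weights (0.12), without the arrays numbered 1 (0.13) and without single arrays (-0.49 to 0), and for Pecam1 without the arrays numbered 1 (0.02) and without single arrays (-0.81 to 0.01). Snai1 (-0.99 to 0.40) and Vegfa (-0.56 to 0.51) turned without single arrays.

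For the difference between stages, genes called were 0 under 13 of 13 alternatives and 0 to 4 without single arrays (4 without early ablation array 3, 1 without early control array 2), and lists called were 5 to 12 without single arrays (5 without late control array 1, 6 without late ablation array 3). The islet call, kept under 3 of 13 alternatives, ended with the larger offset (adjusted p = 0.053), no background correction (0.069), median scaling (0.19), cyclic loess (0.066), the strict filter (0.15), array weights (0.6), the authors' values (0.072) and without the arrays numbered 1 (0.14). Without those arrays the smooth muscle (0.06), collagen (0.15) and endothelial (0.11) calls also ended. Collagen lost its call with the Xist covariate (at -0.31), and B and plasma cell with no filter (0.08). Without single arrays the ductal list ranged from 0.34 to 1.06 (0.34 without early ablation array 1), B and plasma cell from -1.57 to -0.61 (without early ablation arrays 3 and 1) and TGF-beta response from -0.70 to -0.31 (-0.31 without late ablation array 3). Col1a1 ranged from -1.68 to 0.30, Foxp3 from -0.22 to 0.07, and the correlation of the early and the late effect from -0.218 to 0.26.

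Between the controls 0 genes passed. Array weights gave 216 (150 higher, 66 lower), and leaving out single arrays 0 to 2 (2 and 1 without early control arrays 1 and 2). Lists called went from 2 to 4 with only the groups compared and to 1 to 9 without single arrays (1 without early control array 3, 9 without late control array 2). Proliferation kept its call under 12 of 14 alternatives (-0.84 to -0.52). Direction turned for Foxp3 with median scaling (0.02), for Irak1bp1 with the authors' values (0.02) and without single arrays (-1.04 to 0.32), and for Acta2 with the authors' values (-0.02), the Xist covariate (-0.05), without the arrays numbered 1 (-0.45) and without single arrays (-0.45 to 0.79). Col1a1 turned without the arrays numbered 1 (-0.34) and without single arrays (-0.34 to 1.63), Pecam1 (-0.80 to 0.02) and Ctla4 (-0.32 to 0.08) without single arrays.

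With anti-CTLA4 1 gene passed. Counts were 2 with no background correction, 2 with median scaling, 7 with no filter, 5 with all probes, 3 with the trended and robust variance, 18 with array weights, 5 with the authors' values, 64 without the arrays numbered 1, and 1 to 9 without single arrays (9 without late ablation array 1, 5 without anti-CTLA4 array 1). Without the genes between H2-K1 and Mog the count was 0, since the called gene is one of them. Lists called went from 2 to 4 with only the groups compared, 4 with the authors' values, 4 with the Xist covariate, and 1 to 5 without single arrays (1 without late ablation array 2 or anti-CTLA4 array 1 or 2, 5 without late ablation array 3). Without the arrays numbered 1, which leaves late ablation with 2 arrays, collagen stood at -0.34 (adjusted p = 0.26) and proliferation at 0.52 (adjusted p = 0.18). Direction turned for Ctla4 with array weights (-0.02), without the arrays numbered 1 (-0.04) and without single arrays (-0.04 to 0.45), and for Snai1 with array weights (0.09), the authors' values (0.02), without the arrays numbered 1 (0.62) and without single arrays (-0.58 to 0.62). Pecam1 turned with the authors' values (0.02) and without single arrays (-0.33 to 0.15), and Vegfa without single arrays (-0.84 to 0.23). The other genes followed through the alternatives kept their direction. Not followed were Twist1, Cd247, Lpl, Lep and Rhag between the controls, and Prom1, Cd8b1, Klf4, Gcg, Dusp1, H2-Aa, H2-Eb1, H2-Ea, Adm and Xist.

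Equal numbers did not pair arrays in the other comparisons (r of -0.14 to 0.15 early, -0.06 to 0.10 between controls and -0.28 to -0.12 with anti-CTLA4). With the replicate block, genes and lists called were 0 and 12 early, 0 and 10 by stage, 0 and 2 between controls, and 1 and 2 with anti-CTLA4.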

Other observations

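The genes named in this part, among them some that a fixed rule had also picked, and the tests of relations with the acinar level, were chosen after their values were seen.

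Among genes not described so far, Prom1, a stem cell marker, differed by 1.74 (SE 0.649, adjusted p = 0.523) between early ablation and early control arrays. Cd8b1, a chain of the CD8 receptor, differed by -0.996 there (SE 0.417, adjusted p = 0.544). The late minus the early effect was 1.47 (SE 0.564, adjusted p = 0.984) for Klf4. Between late and early controls, glucagon, Gcg, differed by 2.89 (SE 1.13, adjusted p = 0.431). Dusp1, an early response phosphatase, differed by -1.22 (SE 0.584, adjusted p = 0.654) between anti-CTLA4 and late ablation arrays, where immediate early and heat shock genes averaged -0.43 (8 of 11 lower, adjusted p = 0.26). None of these passed the test.

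Of the class II genes, H2-Eb1 read 4.76 to 4.85 on the anti-CTLA4 arrays and 5.50 to 10.81 on the other 12 arrays, and H2-Aa read 4.68 to 5.22 on the anti-CTLA4 arrays. Against late ablation arrays H2-Aa differed by -1.98 (SE 1.04, adjusted p = 0.676) and H2-Ab1 by 0.14 (SE 0.838, adjusted p = 0.983). H2-Eb1, undetected on the anti-CTLA4 arrays, was at least 2.39-fold lower there (adjusted p = 0.686). None of these passed. H2-Ea, which C57BL/6 mice do not transcribe, was 10.35 on early control array 2 and 9.92 on early control array 3, and 4.44 to 5.11 on the other arrays.

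Xist, transcribed from the inactive X chromosome of females, was bright on early control array 1 (10.06), early ablation arrays 2 and 3 (10.43 and 10.37), late control array 3 (11.45), late ablation array 1 (9.83) and anti-CTLA4 array 2 (11.05), and 4.41 to 5.08 on the others. By this gene each group mixed the sexes, and early control and early ablation were not balanced for sex. The Xist covariate named above stands for sex. Adm, a gene induced by hypoxia, read 9.95 on late ablation array 3 and 4.50 to 7.52 on the others.

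The other detected Acta2 probes differed by 1.66, 1.34 and 0.95 between early ablation and early control arrays, with standard errors of 1.01, 1.05 and 1.04. Of the Foxp3 probes, the brightest read 8.77 to 9.43 on all arrays, and another detected one 4.64 to 5.76. The bright Kdm2b probe read 6.51 to 8.21 outside the early control arrays, and its other probes read 4.35 to 5.86, undetected on most arrays.

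Over the 12 arrays of the first table, 21 lists were compared with the acinar level by permutation, and none passed adjustment. The collagen and extracellular matrix list had r = 0.61 (p = 0.034, adjusted p = 0.12) and rho = 0.74 (p = 0.0076, adjusted p = 0.08), and r = 0.81 without the 2 arrays farthest from the acinar median. MHC class II had r = -0.76 (p = 0.0051, adjusted p = 0.067) and rho = -0.45 (p = 0.15, adjusted p = 0.38), and r = -0.66 without the 2 arrays. Pan T cell had r = -0.75 (p = 0.0064, adjusted p = 0.067) and rho = -0.63 (p = 0.033, adjusted p = 0.16), and r = -0.47 without them. Mesenchymal transition had r = 0.58 (p = 0.042, adjusted p = 0.13) and rho = 0.76 (p = 0.006, adjusted p = 0.08), and r = 0.83 without them.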
